A study of Escherichia coli K-12 with 2 samples.

How the data were processed

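RNAs that co-purified with the small RNA CyaR were measured in Escherichia coli K-12 by MS2-affinity purification and RNA sequencing. There were 2 libraries, 1 from cells expressing CyaR fused to the MS2 aptamer and 1 from cells expressing untagged CyaR. The labels put each library in its group by genotype, and the columns of the table were matched to the libraries by their titles. Both labels name exponential and stationary phase, and the table held a single count column per library, so how the phases were combined is not given in the sources used here.

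The authors deposited whole-number read counts per feature, where a feature was a gene or the gap between a pair of neighbouring genes. The deposited normalized columns, which are of another kind of unit, were the count divided by a total for the library, as recomputed from the values. Those totals were 3627815 for MS2-CyaR and 3286911 for CyaR. The deposited ratio column, per the file headers MS2-CyaR over control, held the ratio of the normalized columns rounded to whole numbers, and the largest difference from the unrounded ratio was 0.497. Reads were aligned with Bowtie, per the submitters' processing notes. Its version, the genome build, the annotation, the counting tool and whether counting used the strand are not given in the sources used here. Without strand, reads from overlapping or antisense genes cannot be separated, which concerns symR with symE. For tff and rpsB, which have a gap between them, how reads at the boundaries were counted is not known. Copies of the ribosomal RNA genes share reads, so values of single copies are uncertain. A read that crosses a gene boundary can fall in a gene or in the adjacent gap, so neighbouring features were counted together as loci where stated.

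The table held 6809 features, of which 4117 were genes and 2692 were gaps. Gene names were compared with the RefSeq annotation of assembly ASM584v2, which was used only for names, gene types and the order of neighbours. By symbol 3743 genes matched, by synonym 210 matched, and 164 had no match. No coordinates are given because no build was named. The enrichment of the bait, meant as the first check of the labels, could not be computed, because cyaR was not analysed here. The labels therefore stand unchecked.

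No value in either column was 0. The CyaR column held 3778 features at a count of 1 and 832 at a count of 2, against 987 and 824 in MS2-CyaR. Among 776 features with 21 to 50 counts in MS2-CyaR, 208 had a control count of 1 and 88 a control count of 2. A control count of 1 can therefore stand for 0 reads, and ratios over such counts are read with their intervals.

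From the counts, each library was divided by its total over features other than rRNA and tRNA genes, 176592 for MS2-CyaR and 89675 for CyaR. The ratio of the scaled values was taken with nothing added. A feature passed if it had 50 counts or more in the library with the higher scaled value, which corresponds to 283 counts per 1000000 in MS2-CyaR and 558 in CyaR. Features with a ratio of 4 or more were called higher and those with a ratio of 1/4 or less were called lower. Each ratio has a 95% exact (Clopper-Pearson) interval, obtained from the binomial share of the counts in MS2-CyaR given their sum. With 1 library per group, no test across samples exists, no p-value is given and no difference has a replicate check. The intervals cover counting error only, and amplified reads are not independent molecules.

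There were 20 gene lists, and a list's median log2 ratio was placed among those of 10000 random gene lists of the same size, matched on deciles of the mean scaled value. Random lists were drawn from all genes that passed, the list's own members included. Percentiles are given for the 13 lists with 3 or more passing genes, describe these libraries only, and were read against limits of 2.5 and 97.5. The lists were known CyaR targets, hdeD alone, Hfq-dependent small RNAs, other small RNAs, outer membrane proteins, acid resistance, RpoS-dependent genes, quorum signalling, NAD synthesis, phosphotransferase sugar uptake, the CRP and cyclic AMP genes, the arabinose and maltose genes, flagella and motility, ribosomal proteins, the degradosome with Hfq, the tricarboxylic acid cycle, the sigma E envelope response, ribosomal RNA and transfer RNA. Named features were the 25 with the highest and the 8 with the lowest ratio among those that passed, the known targets and hdeD whatever their values, and from each other list up to 4 passing members, the 2 highest and the 2 lowest. Other genes named in the text were chosen after their values were seen. The scaling, the count minimum, the thresholds, the lists, the naming rule and the first set of other settings were fixed before the data were examined.

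The first set of other settings was the total over all features, median-of-ratios scaling, count minimums of 10 and 200, ratio thresholds of 2 and 8, 10 added to both counts, and random lists matched on the CyaR library or not matched. Settings chosen after seeing the data were the authors' library totals, totals without rpsB, tff, tsf and the first genes of the S10 operon, an equal scaled minimum in both libraries, control counts below 3 raised to 3, genes without gaps, the interval bound in place of the ratio, and the ribosomal protein list without rpsB and the first S10 genes. The authors' totals put every ratio 1.78 times higher than the main scaling does.

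The method was tested on simulated data for this comparison over 6809 features, with 50 features changed at each fold. Of these, 0% were called at 2-fold, 52.0% at 4-fold and 100.0% at 8-fold and at 16-fold, and 0 of 347 unchanged features that passed were called. The simulated counts held counting noise only, around a single profile averaged over the 2 libraries, with changes balanced between them. Features with few expected control counts were not changed. These rates therefore do not carry over to ratios over low control counts or to the choice of scaling. The intervals held the true ratio in 94.5% of cases, and 6.50% of 200 random lists lay beyond the percentile limits. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.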

Results

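The RNAs bound to CyaR in vivo were sampled by MS2-affinity purification. CyaR is a small regulatory RNA that acts with the RNA chaperone Hfq and is transcribed under control of CRP and cyclic AMP. It was expressed with an MS2 RNA aptamer in the MG1655 rne131 strain without its own cyaR gene, in which rne131 encodes a truncated RNase E that lacks its degradosome scaffold. Expression was induced with 0.1% arabinose for 10 min, in cells at an optical density of 0.5 and of 1. Lysate was passed over amylose resin carrying the MS2 coat protein joined to maltose-binding protein, and bound RNA was released with maltose and sequenced. The same purification from cells with untagged CyaR gives the background of RNAs that stay on the column without the tag.

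There were 2 libraries, 1 MS2-CyaR and 1 untagged CyaR, so no difference has a replicate check. The table held 391075 counts for MS2-CyaR and 180432 for CyaR, which is 10.8% and 5.49% of the library totals behind the deposited normalized values. Ribosomal RNA took 54.7% of the MS2-CyaR counts and 50.2% of the CyaR counts. Outside rRNA and tRNA there were 176592 and 89675 counts, and the median feature had 6 counts in MS2-CyaR and 1 in CyaR. The 10 most abundant features held 14.9% of these counts in MS2-CyaR and 38.9% in CyaR. All ratios below are MS2-CyaR over CyaR after scaling to these totals, with 95% counting intervals.

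The first comparison asks which RNAs were recovered with tagged CyaR beyond the untagged background. The highest ratios belonged to yacL, an uncharacterised gene next to the aconitase gene acnB, and to mgrB, which encodes a small membrane protein that restrains the sensor kinase PhoQ. For yacL there were 816 counts against 2, a ratio of 207 (57.2 to 1714), and for mgrB 2245 against 6, a ratio of 190.0 (87.2 to 518). Among genes, the acid-resistance gene hdeD followed with 1540 against 7, a ratio of 112 (54.1 to 278). The gap between acnB and yacL lay above it, with 255 against 1 and a ratio of 129.5 (23.0 to 5134). The adaptor gene clpS of the ClpAP protease had 411 against 2, a ratio of 104 (28.7 to 865), and the sodium-proton antiporter gene nhaA had 706 against 4, a ratio of 89.6 (34.9 to 330).

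The 25 highest features made up 19 loci and had ratios from 60.0 to 207. The ranking depends on low control counts, since 9 of the 25 stayed in it with 10 added to both counts and 13 with control counts below 3 raised to 3, where mgrB came above yacL. With 10 added the log2 ratio of yacL went from 7.69 to 5.13 and that of bolA from 6.79 to 3.40. Several loci carried both a gene and an adjacent gap, as for yacL with the gap toward acnB, clpS with the gap toward clpA, nhaA with the gap toward nhaR, and symR with the gap toward hsdS. The tRNA-modification gene miaA had 1854 counts against 14, a ratio of 67.3 (40.0 to 123), the gap between miaA and hfq had 1415 against 11, a ratio of 65.3 (36.4 to 131), and hfq itself had 1231 against 11, a ratio of 56.8 (31.7 to 114). The gap between araJ and sbcC had 1654 against 14, a ratio of 60.0 (35.7 to 110.0). The ribosomal protein gene rpsT had a ratio of 66.5 (28.4 to 206), and ydcH, of unassigned function, had 259 counts against 2 and a ratio of 65.8 (18.02 to 546).

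Of the 25, 15 rested on a single control count, so their intervals are wide. They include bolA, a stationary-phase regulator of cell shape, with 218 counts against 1 and a ratio of 111 (19.7 to 4392), and the gap between nuoB and nuoA of the NADH dehydrogenase operon, with 220 against 1 and a ratio of 112 (19.8 to 4432). The trans-translation gene smpB had 180 against 1 (16.2 to 3630), the lipid-asymmetry lipoprotein gene mlaA 170 against 1 (15.3 to 3430), and dtd, for a deacylase of mischarged tRNA, 151 against 1 (13.6 to 3048). The gap between ydhC and the cyclopropane fatty acid synthase gene cfa had 157 against 1, as did the gap between uspG and ybdR. The genes yicG, with 132 against 1, and yaaY, with 119 against 1, have no assigned function. The small RNA symR had 129 against 1 (11.6 to 2607), and its reads cannot be separated from those of symE, to which it is antisense, which had 34 against 1.

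Across the table, 688 features had 50 counts or more in the higher library, of which 362 (52.6%) were higher, 99 (14.4%) were lower and 227 lay between. Passing and being called higher are not separate outcomes for every feature. A feature that passed with only a few control counts, such as luxS, tsx, cpdA, pcnB or serU, had to be called higher. A control count of 1 was found for 75 of the higher features. The higher features fell in 225 loci and the lower ones in 56. The lower bound of the interval was above 4 for 230 of the higher features, and the upper bound was below 1/4 for 72 of the lower ones. The median ratio of the features that passed was 4.64, and the split depends on the scaling. Median-of-ratios scaling, taken over these 688 features, puts every log2 ratio 2.21 lower and gives 146 higher and 176 lower, whereas the authors' totals put it 0.84 higher and give 430 and 53. The size of the 2.21 shift depends on the count minimum. The median log2 ratio was 1.02 over features that passed an equal scaled minimum and 1.13 over those that passed a minimum of 200. Under median-of-ratios scaling, any feature with a ratio below 4.64 here, such as treB or gcvB, has one below 1, and a ratio of 18.6 here is needed to reach 4. Of the 48 named features called higher, 34 are also called higher with that scaling, and all 12 called lower are. With the authors' totals all 48 are called higher and 10 of the 12 lower, since tolC, at a log2 ratio of -1.36, and bamB, at -1.46, are then above 1/4. With a minimum that is equal in scaled counts, 177 were higher and 99 lower, since 50 counts is a lower bar in the deeper MS2-CyaR library.

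**Figure D1:**
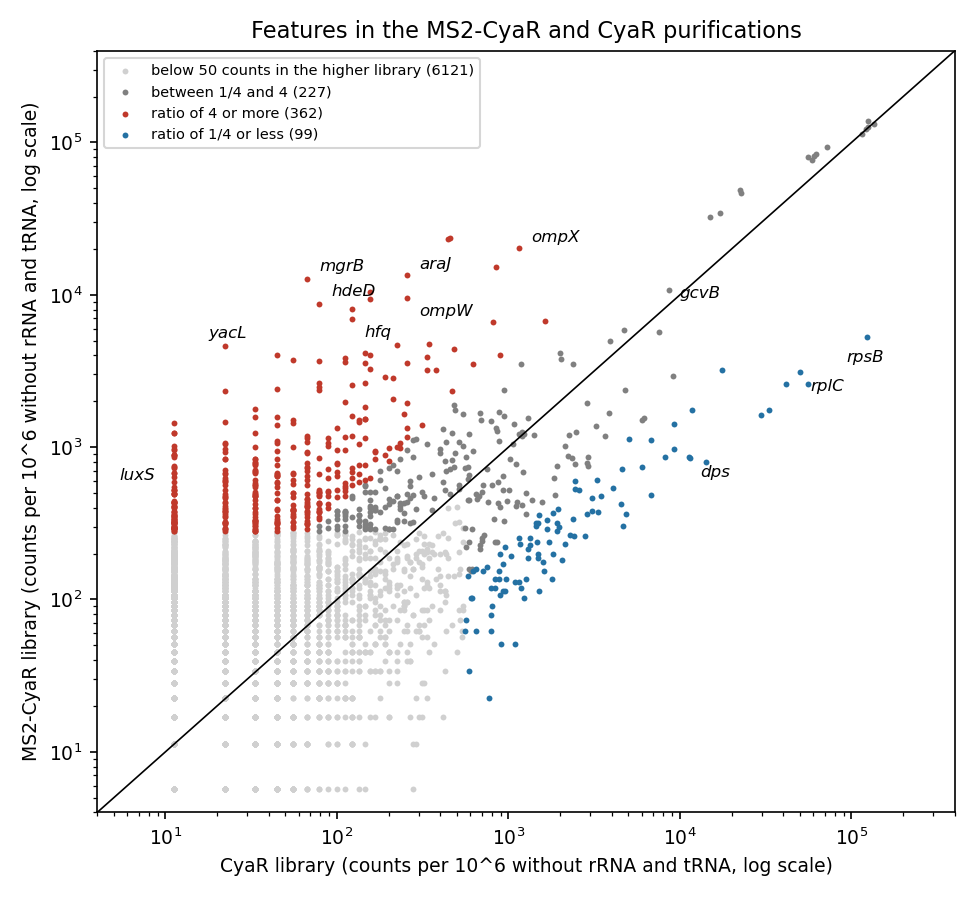
Scaled counts of each feature in the CyaR library (horizontal axis) and the MS2-CyaR library (vertical axis), in counts per 1000000 counts without rRNA and tRNA on log scales, with equal values on the diagonal line. The 362 features with a ratio of 4 or more are red and the 99 with a ratio of 1/4 or less are blue. The column of points at the left edge holds features with a single control count, and rpsB is the rightmost blue point. rRNA genes, at the upper right, are plotted on the same scale although their counts are not in the totals.

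The second comparison asks whether mRNAs already known to pair with CyaR were recovered. All 4 were higher in MS2-CyaR under the main scaling, which for nadE, luxS and yqaE follows from passing the count minimum with 1 or 2 control counts. The outer membrane protein gene ompX had 3595 counts against 103, a ratio of 17.7 (14.6 to 21.8). The NAD synthetase gene nadE had 82 against 2, a ratio of 20.8 (5.58 to 175), the autoinducer synthase gene luxS had 119 against 1, a ratio of 60.4 (10.6 to 2407), and yqaE, for a small membrane protein, had 77 against 1, a ratio of 39.1 (6.81 to 1564). Their median log2 ratio was 4.83, at percentile 98.3 of random lists, whose medians ran from -0.24 to 4.65 between the limits. The percentile was 95.2 with median-of-ratios scaling and 63.5 when random lists were matched on the CyaR library alone, where 3 of the 4 genes had no more than 2 counts. The log2 ratio of ompX was 1.93, under the threshold, with median-of-ratios scaling, that of nadE was 1.96 with 10 added to both counts, and only 2 of the 4 passed an equal scaled minimum. The ratio of hdeD, given above, is not independent evidence, because the group that made the libraries followed this gene up.

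Outer membrane protein genes had ratios on both sides of 1. Of 23 genes listed, 9 passed, and 6 were higher, 1 was lower and 2 lay between. Besides ompX, the nucleoside channel gene tsx had 77 against 1, a ratio of 39.1 (6.81 to 1564), and ompW had 1694 against 23, a ratio of 37.4 (24.8 to 59.2). The porin gene ompF had 568 against 34, a ratio of 8.48, the protease gene ompT 158 against 17, a ratio of 4.72 (2.86 to 8.31), and the lipoprotein gene lpp 245 against 28, a ratio of 4.44 (3.00 to 6.83). The abundant ompC and ompA transcripts had ratios of 1.25 (1.11 to 1.40) and 0.758 (0.687 to 0.837), and the efflux channel gene tolC, with 94 against 219, had 0.218 (0.169 to 0.279). The list's median log2 ratio of 2.24 was at percentile 90.2, and at 98.4 with median-of-ratios scaling and 99.6 with matching on the CyaR library. Under median-of-ratios scaling 2 of its genes were higher and 2 lower, and lpp and ompC fall below 1.

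In the acid-resistance list 3 of 15 genes passed and all 3 were higher. They were hdeD and its neighbours hdeA, with 499 counts against 19 and a ratio of 13.3 (8.45 to 22.3), and hdeB, with 345 against 23 and a ratio of 7.62 (4.99 to 12.2), which encode periplasmic acid chaperones. The list lay at percentile 91.0. With median-of-ratios scaling hdeD alone was called, hdeA being at a log2 ratio of 1.52 and hdeB at 0.72, and with a minimum of 10 counts 13 genes passed, with a median of 2.02 at percentile 77.1. Of 17 RpoS-dependent genes 3 passed. The gene of the stationary-phase sigma factor itself, rpoS, had 206 against 10, a ratio of 10.5 (5.57 to 22.1), and bolA is given above, whereas dps, for the DNA-binding protein of starved cells, had 150 against 1028, a ratio of 0.0741 (0.0620 to 0.0880). The list lay at percentile 90.8, and rpoS is at a log2 ratio of 1.17, under the threshold, with median-of-ratios scaling.

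Genes of sugar uptake by the phosphotransferase system did not stand apart from other genes. Of 9 that passed, 6 were higher and 3 lay between, where 53.8% of all passing genes were higher, and the median log2 ratio of 2.17 lay at percentile 62.2. With median-of-ratios scaling 0 of the 6 that passed were called, and the median was 0.21 at percentile 23.7. With 10 added 1 of 9 was higher. The glucose branch had crr at 79 against 3, a ratio of 13.4 (4.41 to 66.2), and ptsG at 107 against 5, a ratio of 10.9 (4.52 to 34.2). The genes manZ, gatB, gatC and treB had ratios from 5.48 down to 4.13, and ptsH and gatA had 2.00 (1.09 to 3.89) and 1.87 (1.33 to 2.67). The last 2 and ptsI, gatC and treB are below 1 under median-of-ratios scaling. In NAD synthesis 2 of 10 genes passed, nadE and the nicotinate salvage gene pncB, with 102 against 10 and a ratio of 5.18 (2.71 to 11.1), and neither was called with 10 added to both counts. Among 11 quorum-signalling genes luxS alone passed, and of the CRP and cyclic AMP genes only cpdA, for the cyclic AMP phosphodiesterase, passed, with 58 against 1 and a ratio of 29.5 (5.08 to 1183). With 10 added to both counts cpdA was at a log2 ratio of 1.65, under the threshold, and it did not pass an equal scaled minimum.

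The arabinose genes bear on the inducer. Of 8 that passed, araJ, for an arabinose-induced transporter, was higher, with 2390 counts against 23 and a ratio of 52.8 (35.1 to 83.4), and 7 lay between. With the authors' totals 6 of the 8 were called higher, and with a threshold of 2 also 6. The transport genes araH, araF and araG had 3.92 (2.85 to 5.52), 1.08 (0.699 to 1.70) and 0.564 (0.432 to 0.737). The list lay at percentile 71.1, and its median log2 ratio of 1.36 is -0.77 under median-of-ratios scaling. In the maltose list only malK passed, with 86 against 25 and a ratio of 1.75 (1.11 to 2.85). No flagellar or motility gene passed, and the master regulators flhC and flhD had 27 against 1 and 26 against 1.

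**Figure D2:**
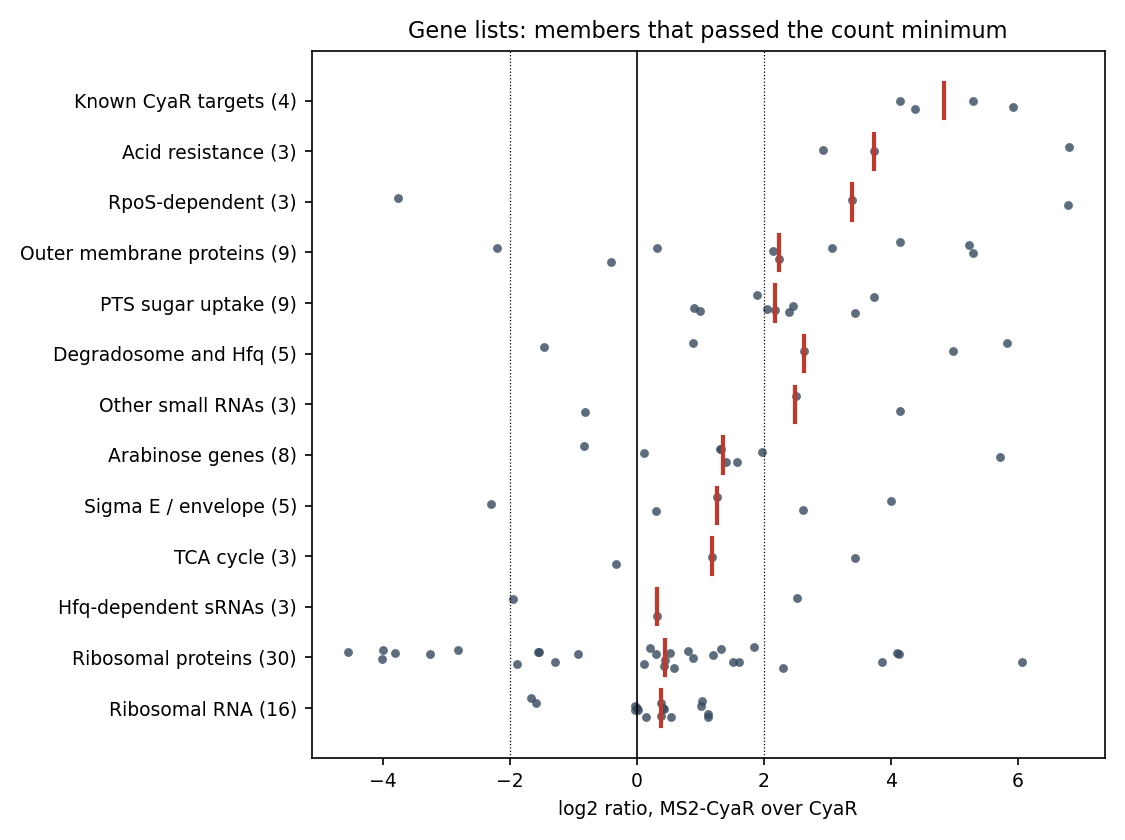
Log2 ratio of MS2-CyaR over CyaR for each passing member (point) of the 13 gene lists with 3 or more such members, with the number of members beside the list's name. Red bars are list medians, the solid line marks equal values and dotted lines mark ratios of 1/4 and 4. The 4 known targets have a median of 4.83 and the 30 ribosomal protein genes, spread over both sides, one of 0.44.

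Other small RNAs were sparse in the table. Of 20 Hfq-dependent small RNAs 3 passed. Spot 42, listed as spf, was higher with 57 against 5, a ratio of 5.79 (2.34 to 18.5), but it was not called with median-of-ratios scaling, at a log2 ratio of 0.32, with 10 added, at 1.18, or with totals without rpsB and the first S10 genes. The amino acid transport regulator GcvB, listed as gcvB, had 1902 against 776, a ratio of 1.25 (1.14 to 1.36), and fnrS, induced without oxygen, had 133 against 261, a ratio of 0.259 (0.208 to 0.320). The list lay at percentile 28.5, and its median log2 ratio of 0.32 is -1.90 under median-of-ratios scaling and 2.53, at percentile 79.1, over the 5 members with 10 counts or more. Of 18 other small RNAs 3 passed. The CsrA-binding RNA csrB had 349 against 10, a ratio of 17.7 (9.52 to 37.3), the RNase P RNA rnpB had 167 against 15, a ratio of 5.65 (3.33 to 10.3), and the tmRNA gene ssrA had 0.569 (0.419 to 0.774). That list lay at percentile 82.6, and 0 of its 3 passing members were higher with median-of-ratios scaling.

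Among RNA decay and chaperone genes, 3 of the 5 that passed were higher. They were hfq, the poly(A) polymerase gene pcnB, with 62 against 1 and a ratio of 31.5 (5.45 to 1263), and the oligoribonuclease gene orn, with a ratio of 6.18. The enolase gene eno had 1.85 (1.01 to 3.62), below 1 under median-of-ratios scaling, and rne had 0.363 (0.242 to 0.540). The list lay at percentile 49.0. With 10 added to both counts 1 of the 5 was higher, pcnB being at a log2 ratio of 1.73, and with an equal scaled minimum 2 passed and 1 was higher.

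Ribosomal protein genes went in opposite directions. Of 30 that passed, 5 were higher, 6 were lower and 19 lay between. The split depends on the scaling, with 1 higher and 11 lower of 17 under median-of-ratios scaling and 10 higher and 5 lower of 30 under the authors' totals. The higher ones were rpsT, rpmA, with 69 against 2 and a ratio of 17.5 (4.67 to 148), rplU at 17.2 (7.76 to 47.4), rpsO at 14.5 (5.50 to 54.0) and rpsK at 4.96 (3.60 to 6.98). The lower ones were rpsB and the first genes of the S10 operon, rpsJ, rplC, rplD, rplW and rplB. With a median log2 ratio of 0.44, above 0, the list nonetheless lay at percentile 1.4 of random lists, whose medians ran from 0.58 to 2.92. The percentile was 16.0 with median-of-ratios scaling, where the median log2 ratio of the 17 passing genes was -3.74, and 6.1 with an equal scaled minimum.

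The abundant transcript of rpsB, for a protein of the small ribosomal subunit, had 935 counts in MS2-CyaR and 11114 in CyaR, a ratio of 0.0427 (0.0399 to 0.0457). Across the S10, spc and alpha operons the ratio went up and down. It was 0.105 at rpsJ, 0.0623 (0.0569 to 0.0681) at rplC, 0.142 (0.105 to 0.190) at rplB and 1.84 (1.12 to 3.14) at rplP. Further on it was 0.412 (0.288 to 0.587) at rplE, 4.96 at rpsK and 0.592 (0.301 to 1.18) at rplQ, the last below the count minimum. The 8 lowest features also held the gap between rpsB and tsf at 0.0462 (0.0419 to 0.0509), the small RNA tff upstream of rpsB at 0.0534 (0.0474 to 0.0601), the gap between them at 0.0543, and the gap between rplD and rplC at 0.0564. Reads that cross the boundaries among tff, the gap and rpsB cannot be assigned without knowledge of how they were counted. Together rpsB, tff, tsf, the first S10 genes and the gaps among them, 13 features, held 34473 control counts (38.4% of the total without rRNA and tRNA) against 3694 (2.09%) in MS2-CyaR.

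The other lowest features were the gap between galK and galT, with 4 counts against 69 and a ratio of 0.0294 (0.00780 to 0.0788), the gap between dmsD and clcB, with 9 against 98 (0.0207 to 0.0922), and the copper homeostasis gene cutC, with 9 against 81 and a ratio of 0.0564 (0.0249 to 0.113). All 4 genes of the galactose operon were lower, with galK at 0.0938 (0.0670 to 0.129) and galM at 0.2204 (0.158 to 0.304). In the trehalose operon treB had 1188 against 146, a ratio of 4.13 (3.48 to 4.94), and treC had 564 against 1582, a ratio of 0.181 (0.164 to 0.199). Of 86 adjacent gene pairs in which both were called, 6 were called in opposite directions, against 2 of 54 with median-of-ratios scaling, 4 of 95 with the authors' totals and 1 of 44 with 10 added. The trehalose pair is opposite only in the main setting among these.

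**Figure D3:**
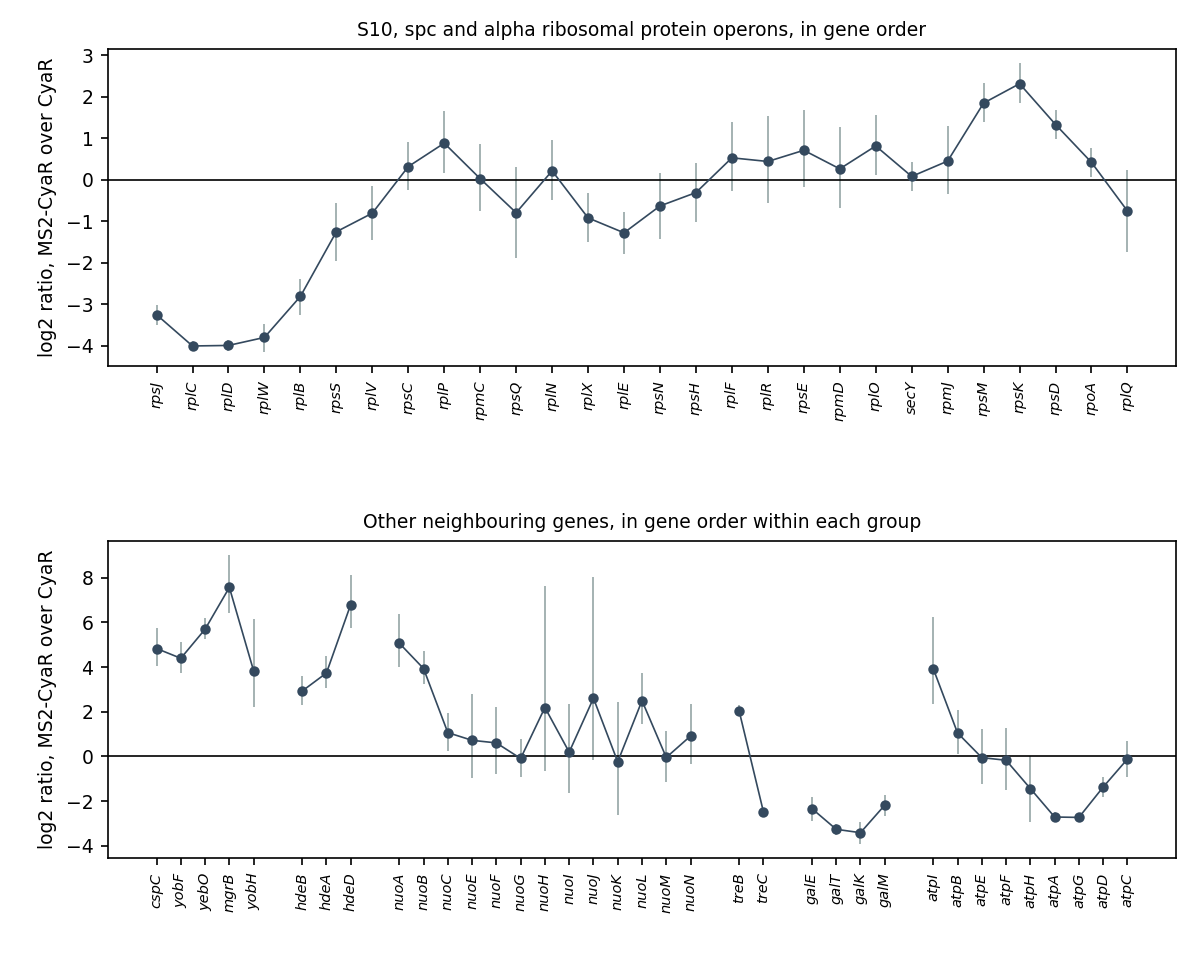
Log2 ratio of MS2-CyaR over CyaR, with 95% counting intervals as bars, for the genes of the S10, spc and alpha ribosomal protein operons in order (top) and of other groups of neighbouring genes (bottom). The line at 0 marks equal scaled values. Ratios run from 0.0623 at rplC to 4.96 at rpsK in the top panel, and galactose genes all lie below the line.

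In the tricarboxylic acid cycle 3 of 17 genes passed. The malate dehydrogenase gene mdh was higher, with 128 against 6 and a ratio of 10.8 (4.84 to 30.1), and acnB had 2.29 (1.21 to 4.69) and lpd 0.794 (0.574 to 1.10). The list lay at percentile 19.1, and at 2.4 with a minimum of 10 counts, and mdh is at a log2 ratio of 1.22 with median-of-ratios scaling. In the sigma E list 5 of 16 genes passed, and rpoE itself had 191 against 6, a ratio of 16.2 (7.29 to 44.6). The genes of the outer membrane assembly machine differed, with bamA at 6.09 (2.67 to 17.2), bamC at 1.24 (0.9501 to 1.63) and bamB at 0.204 (0.158 to 0.260), and the list lay at percentile 32.2. With median-of-ratios scaling rpoE, at a log2 ratio of 1.80, and bamA, at 0.39, are not called.

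All 16 ribosomal RNA genes that passed lay between the thresholds, from 2.18 (2.06 to 2.32) at rrsD to 0.316 (0.205 to 0.482) at rrfF. Of the 16, 7 were called lower with median-of-ratios scaling and 2 with totals without rpsB and the first S10 genes. Copies share reads, and these genes did not enter the scaling totals. Their list lay at percentile 74.5, at 99.8 with median-of-ratios scaling, at 100.0 when matched on the CyaR library and at 1.9 without matching. Matched random lists can hold these abundant genes themselves, so the percentiles weigh the list partly against its own members. The list's median log2 ratio of 0.38 is -1.83 with median-of-ratios scaling. Of 68 tRNA genes in the table only serU passed, with 117 against 2 and a ratio of 29.7 (8.04 to 248).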

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

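The authors' totals, the totals without rpsB and the first S10 genes, the equal scaled minimum, the raised control counts, the genes without gaps, the interval bound and the shortened ribosomal list were chosen after seeing the data. Against 362 higher features in the main setting, there were 146 with median-of-ratios scaling, 1238 and 74 with minimums of 10 and 200 counts, 157 with 10 added to both counts, 177 with an equal scaled minimum and 230 by the interval bound. Against 99 lower features there were 176 with median-of-ratios scaling, 182 and 36 with minimums of 10 and 200, 45 at a threshold of 8 and 53 with the authors' totals. Other settings stayed within 1.5 times the main counts. A higher or lower minimum changes which features can be called, and another scaling shifts every log2 ratio by a fixed amount. For the other settings the cause was not tested.

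List percentiles crossed a limit as follows. Known targets, 98.3 in the main setting, were at 95.2 with median-of-ratios scaling and 63.5 with matching on the CyaR library. Outer membrane proteins, 90.2, were at 98.4 and 99.6. Ribosomal RNA, 74.5, was at 99.8 and 100.0, and at 1.9 without matching. Ribosomal proteins, 1.4, were at 16.0 with median-of-ratios scaling and 6.1 with an equal minimum, and at 0.7 without rpsB and the first S10 genes. The tricarboxylic acid cycle, 19.1, was at 2.4 with a minimum of 10. The median log2 ratio of ribosomal proteins, 0.44, reversed to -3.74 with median-of-ratios scaling, -2.35 with a minimum of 200 and -1.53 with an equal minimum. The minimum of 200 and the equal minimum leave each ratio as it was and change only which genes passed, 12 and 17 against 30. Median-of-ratios scaling lowers every log2 ratio by 2.21, and 17 genes passed with it. A fixed shift does not reorder genes, so percentiles moved with the genes that passed, the matching, or both. No further cause was tested.

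Of 79 named features, none that was called changed direction under median-of-ratios scaling, the total over all features, the authors' totals, totals without rpsB and the first S10 genes, or 10 added counts. This was nearly fixed in advance, because a call needs a ratio of 4 or 1/4. The authors' totals shift every log2 ratio by 0.84, and totals without rpsB and the first S10 genes by -0.67. Under median-of-ratios scaling only called ratios from 4 to 4.64 can reverse. The higher genes treB, gatC and lpp, not among the 79, fall below 1 there. Values of the named features left the main interval in 60, 5, 30, 30 and 42 cases, in that order of settings. Calls were lost: of 48 called higher, 34, 48, 48, 44 and 38 were still called so, and of 12 called lower, 10 with the authors' totals, without tolC and bamB, and 12 with the others. A minimum of 200 left 21 of 48 and 9 of 12, an equal scaled minimum 39 and 12. A threshold of 8 left 43 and 10, and the interval bound 44 and 10. Of the 25 highest, 9 were shared with 10 added and 13 with control counts below 3 raised to 3. Leaving out a replicate was not possible with 1 library per group. Phases could not be taken alone, because the table has 1 column per library. The total without cyaR equals the main total, and alternatives for the bait gave no value, because the bait was not analysed here.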

Other observations

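The genes in these paragraphs were chosen after their values were seen. Of 14 genes with an fts name, 9 passed, 7 were higher and 2 lay between, against 53.8% higher among all 530 genes that passed, a difference that was not tested. The signal recognition particle receptor gene ftsY had 172 counts against 2, a ratio of 43.7 (11.9 to 364), the cell wall polymerase gene ftsW 139 against 3, a ratio of 23.5 (7.89 to 116), and ftsE, of the ABC-type division complex, 114 against 4, a ratio of 14.5 (5.500 to 54.0). The gene of the division ring protein, ftsZ, had 199 against 26, a ratio of 3.89 (2.58 to 6.10), and it and ftsA are below 1 under median-of-ratios scaling. The peptidoglycan endopeptidase gene mepS had 568 against 30, a ratio of 9.62 (6.66 to 14.4).

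In the ribose operon the permease gene rbsC had 709 counts against 14, a ratio of 25.7 (15.2 to 47.3), and rbsB, for the ribose-binding protein, 1178 against 73, a ratio of 8.20 (6.47 to 10.5). The ATPase gene rbsA of the same operon had 17 against 22, below the count minimum. The toxin gene mqsR had 104 against 2 and its antitoxin gene mqsA 87 against 1. In the stretch from cspC to mgrB, yebO had 4091 against 40, a ratio of 51.9 (38.1 to 72.8), and cspC 730 against 13, a ratio of 28.5 (16.6 to 53.8). Of 5 Hfq-dependent small RNAs with 10 counts or more, 3 had a ratio of 4 or more, 60.0% (exact Clopper-Pearson interval 14.7% to 94.7%), against 46.3% of 1920 genes at that minimum. Of these, micA, with 36 against 1, and sdsR, with 16 against 1, had to reach 4 once they passed. Their ratios have intervals of 3.08 to 742 and 1.26 to 341. The interval of the share treats the small RNAs as independent within 1 pair of libraries, so no conclusion is drawn from it.

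The tests that follow were chosen, or their criteria revised, after the results were seen. The high ratio of araJ is set against the inducer. If a difference in induction made its ratio and acted equally on all arabinose genes, which is assumed, the others would move as araJ did. Their median ratio was 2.49 over 8 genes and their highest upper bound 5.52, which argues against a shared difference of that size. A smaller difference in induction stays open. The intervals of araA, araB, araC, araE and araH lay above 1, those of araD and araF spanned 1, and that of araG lay below 1. The lower bound of araJ, 35.1, argues against counting error in the control. The gap between araJ and sbcC shared the high ratio, whereas sbcC had 29 against 7, a ratio of 2.10 (0.902 to 5.69). Pairing of araJ mRNA with CyaR is a hypothesis that was not tested.

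The low ratios of rpsB and the first S10 genes are not made by their own weight in the control total, since leaving them out of the totals changes every log2 ratio by -0.67. A yield loss of this size shared by all ribosomal protein mRNAs was also considered. The lower quartile of all 54 in the table, taken without a filter, was 0.580, and that of the 38 with 50 counts over both libraries was 0.414. Both lie above the highest upper bound of the 13 low features, 0.190. These features hold the 6 ribosomal protein genes with the lowest ratios, so that outcome was nearly fixed in advance and does not weigh a shared loss. Of the other 24 ribosomal protein genes that passed, 5 were higher under the main scaling, with a lower quartile of 1.14. That 0 were lower is fixed, because the 6 set apart are all that were called lower. Under median-of-ratios scaling 11 of the 17 that passed, these 6 included, were lower. Most of the 24 lay far above 0.190 under the main scaling, but calls among them depend on the scaling. The median log2 ratio of the 24 was 0.70, above 0, but at percentile 0.7 of random lists, so a smaller shared loss stays open. A difference between the cultures or libraries other than the tag stays open too, because there was 1 library per group. No biological explanation was tested.

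The median log2 ratio of the features that passed was 2.21 (bootstrap interval 1.93 to 2.44). The bootstrap intervals here describe the spread over features, which are not independent where neighbours share reads. With 1 library per group they hold no spread between libraries. An equal scaled minimum gave 1.02 (0.53 to 1.67), which is lower but does not reach 0 under the main totals. The unequal depths stay open as a part of the cause and are not shown to be the whole. Totals without rpsB and the first S10 genes gave 1.63 (1.39 to 1.83), which argues against these features alone in these 2 libraries. Both changes together gave -0.82 (-1.49 to -0.35), where the totals alone lower every log2 ratio by a fixed amount (-0.67). The combined value passes 0 and does not single out a cause, so the sign of this median depends on these choices and its origin stays open.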
